A study of Homo sapiens with 8 samples.

How the data were processed

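Stranded, poly(A)-selected libraries were made from total RNA of SKOV3 cells with an Illumina TruSeq kit, per the labels' protocols. The deposited tables, gene counts and FPKM (fragments scaled to gene length and library size), each hold 22554 features for the 8 samples. The submitters' processing notes name HISAT2, featureCounts, DESeq2 1.26.0 and the GRCh38 build, without saying what each was used for; the annotation and the counting settings are not given in the sources used here.

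The deposited count table holds whole numbers that behave like estimated counts. Among values of 1 to 20, 55.17% were even. A count was 0 wherever the FPKM was 0 except in 2 values, and 32 features were at 0 in some libraries and above 100 on average in the others. It also names 2557 features by assembly identifiers (MSTRG) that carry no gene name and 607 by an Ensembl identifier alone. The values were therefore handled as estimated counts; they were already whole and needed no rounding. The deposited FPKM values were scaled by the authors to gene length and library size and were used only in alternatives. Where overlapping genes share reads, estimated counts can move from one to the other, which bears on read-through genes in particular. Coordinates and exon counts came from GENCODE release 29 on GRCh38, matched by gene symbol or identifier for 19377 features.

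Groups and sample numbers came from the sample titles. Pairs of libraries within a group differed by 6.83 to 28.9 in chi-square per degree of freedom over genes, far above sampling noise, so no library was counted as a repeat of another, and log2 CPM correlated between 0.979 and 0.986 across genes for all pairs. The common biological coefficient of variation was 12.6%. Total counts were 41203544, 37189698, 38852294 and 44883561 in control samples 1 to 4 and 36780334, 34682501, 34748577 and 34710281 in LDL samples 1 to 4. Intervals and limits for counts of 0 cover counting error only, and a limit is 3 counts of a library's total.

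Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts, with TMM normalization, the default filterByExpr filter (15432 features kept), robust dispersion and group as the only term. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, 20 on biology and 10 as checks, most of them on other cell types, RNA quality or handling, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the 27 lists with at least 5 tested members. Camera with an estimated correlation and fry stood beside it. Members were also adjusted over the list alone. List levels per sample are means of log2 CPM over members, relative to the mean of all libraries. Single genes were compared with exact two-sided permutation tests, in which 4 against 4 samples cannot go below 0.0286.

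The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes FOXQ1; then the protein-coding genes past the threshold with a mean of at least 1 CPM and no overlap between groups, up to 10 in each direction by log2 fold change; then up to 3 called members of each biological list, or its member with the smallest p; and the member with the smallest p of each other list. It named 36 genes. Other genes named in the text, such as ID2, SREBF2, STARD4, IDI1, FDFT1, SQLE, EBP, ABCA1, VIM, SNAI2, ZEB1, LTBP3, SMAD7, WWC1, GAPDH and MT-ND5, were chosen after their values were seen, as examples of their lists.

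Alternatives fixed in advance were DESeq2 size factors and upper-quartile factors in edgeR, other count filters, DESeq2 1.42.0, limma voom, the replicate number as a block, leaving out each sample, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no minimum, a 2-fold threshold, a test against a 1.2-fold change, and other list tests. Added after seeing the data were sample quality weights, thinning of all libraries to equal totals, a smooth correction for GC content and transcript length, an unadjusted p with a 1.5-fold change, the TGF-beta list without ID1, ID2 and ID3, and the addition of PRSS53 to its overlapping gene.

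The gene test was checked on 5 simulated data sets with the means and library sizes of the LDL and control samples and 200 of 15432 genes changed, 50 at each fold size. It called 26.8% of genes changed by 1.25-fold, 66.8% at 1.5-fold, 78.4% at 2-fold and 93.2% at 4-fold, and 7.27% of called genes had not been changed. A list shifted by 0.2 on the log2 scale was called in 5 of 5 data sets. Genes were drawn independently of each other and no sample was made to stand apart. The check therefore does not cover lists with correlated members or outlying samples. It also changed 200 genes, where the data gave 10 calls. With more changed genes the Benjamini-Hochberg adjustment sets a laxer cutoff on p, so the shares called may be too high for these data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.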

Results

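Messenger RNA was sequenced from SKOV3 cells, an established human ovarian cancer line, in 8 samples. In 4 of them low-density lipoprotein (LDL), the main carrier of cholesterol in blood, had been added at 50 µg/mL for 48 h, and 4 control samples grew in plain medium. Total counts ran from 37189698 to 44883561 in the control samples and from 34682501 to 36780334 in the LDL samples, so every LDL library was shallower than every control library. Between 17295 and 17610 features had a count above 0. ERBB2, the receptor gene known to be amplified in this line, stood at 2590 ± 133 CPM in control and 2515 ± 392 CPM in LDL samples (SD, n = 4 each). CDKN2A, which the line is known to have lost, had a count of 0 in all 8 libraries, which allows up to 3 counts, or 0.0668 to 0.0865 CPM depending on the library. The labels do not say whether the 4 samples of a group were separate cultures, so the p-values below measure the spread between these samples, which may be technical.

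The series title names FOXQ1, a forkhead transcription factor linked to invasion of carcinoma cells, as a gene raised by LDL, and its level was compared first. FOXQ1 (ENSG00000164379) lies on chromosome 6 from 1312440 to 1314748 on the plus strand of GRCh38 and is annotated with 1 exon. Its counts were 413, 371, 364 and 495 in control samples 1 to 4 and 433, 531, 527 and 695 in LDL samples 1 to 4. That is 10.1 ± 0.72 CPM in control and 15.57 ± 3.38 CPM in LDL samples (SD, n = 4 each), and all 4 LDL samples lay above all 4 control samples. The ratio was 1.54-fold (log2 fold change 0.62, SE 0.134, 95% interval 0.34 to 0.91). The exact two-sided permutation p for this gene alone was 0.0286, the smallest that 4 against 4 samples can give. Over all 15432 genes tested, the quasi-likelihood test of edgeR gave an adjusted p of 0.169, which missed the threshold of 0.05, and FOXQ1 ranked 24 by p. Among genes at least 1.5-fold higher it ranked 3. LDL sample 1 held the lowest level of the 4 at 11.71 CPM and LDL sample 4 the highest at 19.95 CPM. Without LDL sample 1 the log2 fold change was 0.74 with an edgeR adjusted p of 0.0055. With each sample left out in turn, the log2 fold change ran from 0.48 to 0.74 and the edgeR adjusted p from 0.0055 to 0.743. DESeq2, the tool named in the submitters' processing notes, gave 0.62 with an adjusted p of 0.0146, and over the settings that test against no change the adjusted p ran from 0.0055 to 0.743.

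**Figure D1:**
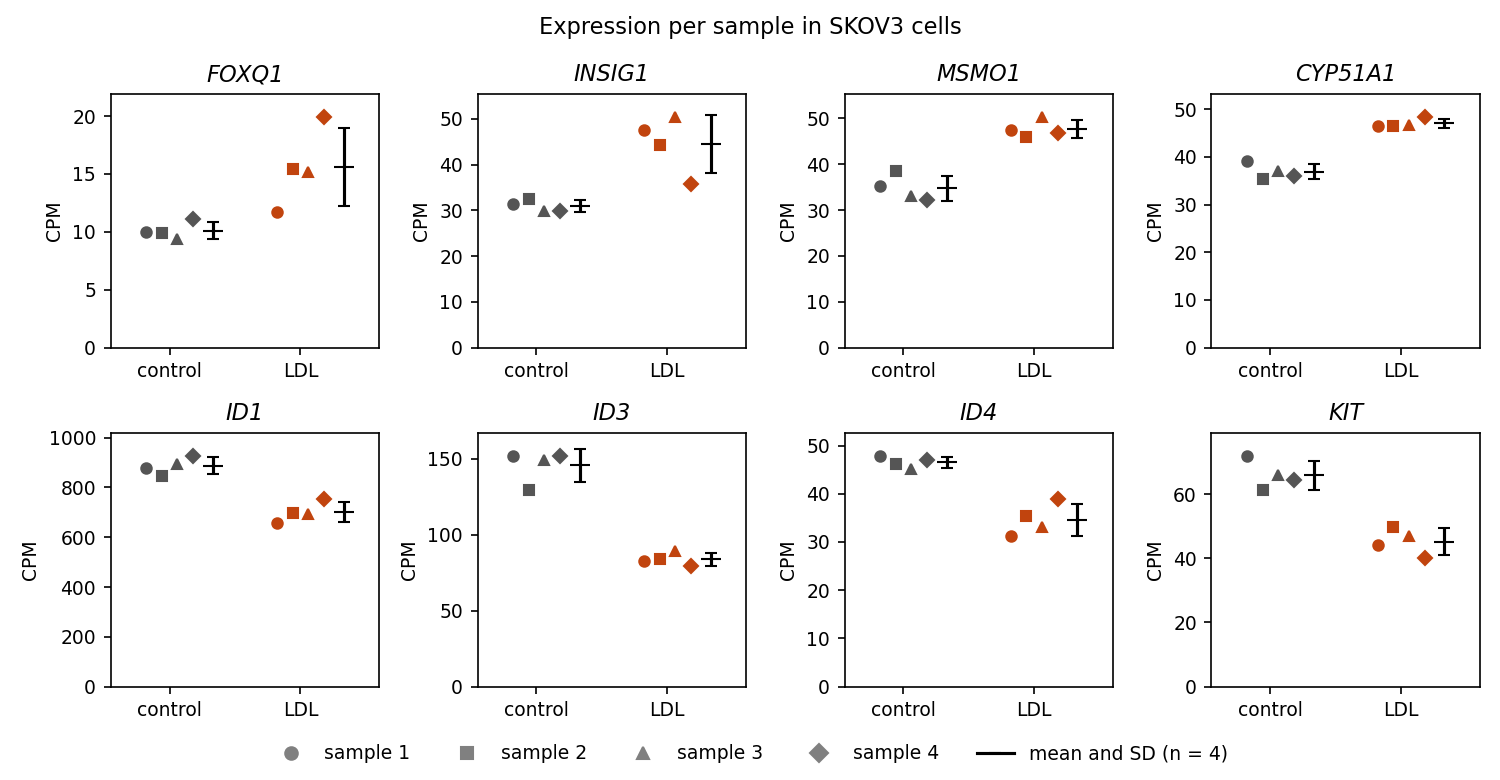
Expression in CPM (counts scaled to library size, y axis from 0) of FOXQ1 and of 7 genes past the threshold, with 1 point per sample, the marker shape giving the sample number, and the mean with its SD (n = 4) beside each group. FOXQ1 lay between 11.71 and 19.95 CPM in LDL samples against 9.40 to 11.11 CPM in controls; the other 3 genes of the upper row were higher and the 4 of the lower row lower in every LDL sample than in every control.

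Across the genome the change was small. Of 15432 genes tested, 4 rose (PRSS53, INSIG1, MSMO1 and CYP51A1) and 6 fell (ID3, KIT, IGFN1, ID4, ID1 and PTPRJ) at an adjusted p under 0.05 in edgeR. The groups did not overlap in any of the 10, and of these only PRSS53 changed by 2-fold or more. At an unadjusted p under 0.05 there were 444 higher and 419 lower genes, 863 in all, where 771.6 are expected by chance. Non-overlapping groups were found for 532 genes, or 3.45%, against 2.86% by chance. The number of calls depended on each library: leaving out control samples 1, 2, 3 and 4 in turn left 3, 6, 2 and 5 genes, and leaving out LDL samples 1, 2, 3 and 4 gave 149, 3, 6 and 26. ID3 and PRSS53 were past the threshold in all 8 of these fits, and DESeq2 called 47 genes, 17 higher and 30 lower, among them all 10. With the replicate number as a block, or with FPKM values and no minimum, only ID3 and PRSS53 of the 10 stayed past the threshold.

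LDL samples 1 and 4 each stood apart, in different ways. LDL sample 4 lay farthest out on the first principal component, at -46.05 against -1.856 to 17.37 for the other 7. To see how far each sample followed the change in the others, the 149 genes with the lowest p in a fit without that sample, of which 146 to 148 were also tested in all 8, were used to place it between the mean of the controls (0%) and the mean of the LDL samples (100%) of the other 7. LDL samples 2, 3 and 4 lay at 75.3%, 69.0% and 56.0%, and control samples 1 to 4 at 27.6%, 33.8%, 8.04% and 30.7%, while LDL sample 1 lay at -14.2%. Among the 149 genes called without it were FOXQ1, all 10 genes named above, IDI1 and FDFT1 of cholesterol synthesis and the cholesterol exporter gene ABCA1. That fit was not corrected for GC content or transcript length.

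**Figure D2:**
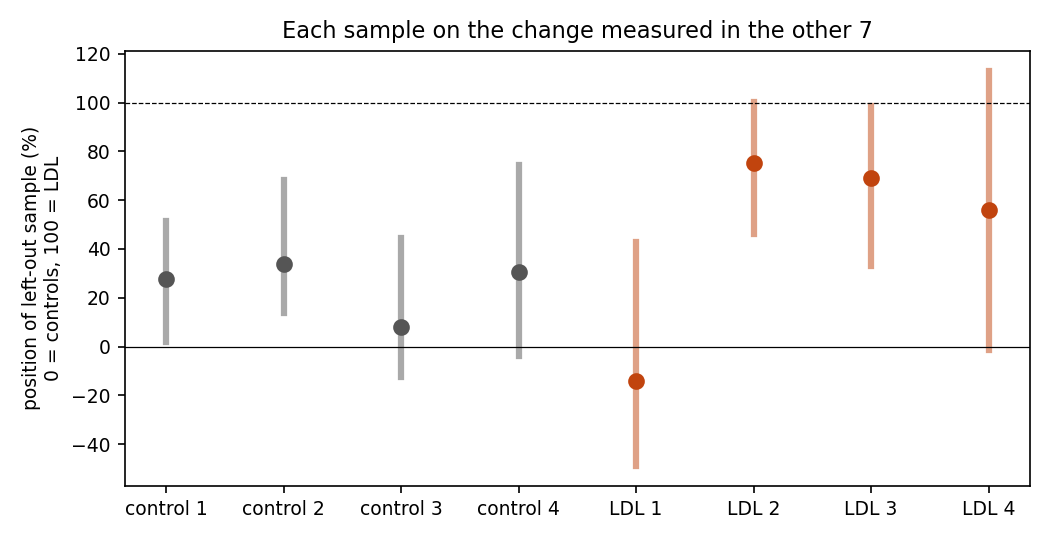
Position of each sample (x axis) on the change measured in the other 7 samples, in percent (y axis, 0 for the mean of the controls and 100 for the mean of the LDL samples), as the median over genes (point) and the middle range from the 25th to the 75th percentile (bar). LDL sample 1 lay at -14.2% and the other LDL samples between 56.0% and 75.3%. The values shown were not corrected for GC content or transcript length, and with that correction LDL sample 1 lay at 9.45%.

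Genes of cholesterol synthesis rose together. INSIG1, whose protein holds the sterol-sensing SREBP complex in the endoplasmic reticulum, rose from 30.9 ± 1.27 to 44.59 ± 6.36 CPM (SD, n = 4 each; 1.44-fold, log2 fold change 0.53, SE 0.0889, edgeR adjusted p = 0.0347). MSMO1, the sterol C4-methyl oxidase, rose from 34.76 ± 2.77 to 47.68 ± 1.93 CPM (1.37-fold, edgeR adjusted p = 0.0114, n = 4 each). CYP51A1, the lanosterol demethylase, rose from 36.92 ± 1.62 to 47.05 ± 0.949 CPM (1.27-fold, edgeR adjusted p = 0.0347, n = 4 each). All 22 listed enzymes of the mevalonate and sterol pathway were tested, and 19 had a log2 fold change above 0, with a median of 0.22. MSMO1 and CYP51A1 passed over all genes, and 15 members were higher when adjusted over the list alone, among them IDI1 (1.32-fold), FDFT1 (1.21-fold) and SQLE (1.21-fold). EBP, at 0.836 of its control level, was the lowest member and did not pass either adjustment. Tested against all other genes by camera with a preset correlation, the list had an adjusted p of 1.69e-12, and with an estimated correlation the adjusted p was 0.0046. Of the lists past the threshold, this was the only one that stayed past it with an estimated correlation. The calls of INSIG1 and CYP51A1 were each lost when any control sample, LDL sample 2 or LDL sample 3 was left out (adjusted p from 0.0874 to 0.278), and that of MSMO1 without control sample 1, 3 or 4 or LDL sample 2 or 3 (0.0522 to 0.142). Limma voom and FPKM values with pseudocounts of 1 and 0.1 also lost INSIG1 (adjusted p = 0.148, 0.185 and 0.201) and CYP51A1 (adjusted p = 0.0649, 0.107 and 0.103). With any 1 sample left out, the list's median stayed between 0.19 and 0.24.

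Further lipid gene lists were tested in the same way. The list of LDL uptake and sterol regulation had a median log2 fold change of 0.077 over 18 tested genes and passed camera with a preset correlation (adjusted p = 0.0142), but not with an estimated one (adjusted p = 0.37). INSIG1 was its 1 member past the threshold over all genes, and 4 members were higher when adjusted over the list alone. Among them were INSIG1, STARD4, a sterol carrier (log2 fold change 0.33), and SREBF2, which encodes the master regulator of sterol synthesis (0.17). The list's call was lost without control sample 1 (adjusted p = 0.111) and without LDL sample 1 (adjusted p = 0.312). No member of the fatty acid synthesis list passed over all genes and 1, the desaturase gene SCD, passed over the list alone (log2 fold change 0.33). The list had a median of 0.060 and a camera adjusted p of 0.119, and it passed without LDL sample 4 (0.0841, adjusted p = 0.0276) and after GC and length correction (0.0777, adjusted p = 0.0124), both with a preset correlation; with an estimated one the adjusted p over all 8 samples was 0.458. Targets of the liver X receptors, which respond to oxidised sterols, had a median of 0.054 (adjusted p = 0.818). Within that list ABCA1, the cholesterol exporter, stood at 26.5 CPM in control and 20.88 CPM in LDL samples (n = 4 each) with an edgeR unadjusted p of 0.0143. Lipid droplet genes, with G0S2 at 1.28-fold, had a median of 0.036 (adjusted p = 0.308). Fatty acid oxidation and PPAR targets, with ANGPTL4 at 1.39-fold, had a median of 0.028 (adjusted p = 0.743).

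ID genes, which encode helix-loop-helix proteins that block differentiation factors and are classical targets of SMAD signalling, fell. ID3 fell from 145.6 ± 10.8 to 83.72 ± 4.12 CPM (SD, n = 4 each), to 0.575 of control (log2 fold change -0.80, SE 0.060, edgeR adjusted p = 4.06e-06). ID1 fell from 886.5 ± 33.9 to 700.7 ± 38.7 CPM (0.790 of control, edgeR adjusted p = 0.00818, n = 4 each). ID4 fell from 46.52 ± 1.2 to 34.66 ± 3.32 CPM (0.745 of control, edgeR adjusted p = 0.0312, n = 4 each). ID2 stood at 15.32 ± 0.834 in control and 10.74 ± 1.17 CPM in LDL samples without passing over all genes (edgeR adjusted p = 0.109, n = 4 each). Of 21 tested TGF-beta target genes 17 had a log2 fold change below 0, with a median of -0.14. ID1 and ID3 fell over all genes, and 6 members were lower when adjusted over the list alone: ID1, ID2, ID3, LTBP3, IGFBP3 and SMAD7. The list passed camera with a preset correlation (adjusted p = 5.08e-07), but not with an estimated one (adjusted p = 0.145). Without ID1, ID2 and ID3, a choice made after the values were seen, the median was -0.10 (camera adjusted p = 0.00236 with a preset correlation; an estimated one was not run for this shorter list). The call of ID1 was lost without control sample 1, 3 or 4 or LDL sample 2 or 3 (adjusted p from 0.0514 to 0.0965), and that of ID4 without any control sample, LDL sample 2 or LDL sample 3 (0.125 to 0.158). Limma voom (adjusted p = 0.0663) and FPKM values with pseudocounts of 1 and 0.1 (adjusted p = 0.107 and 0.109) also lost ID4. LDL sample 4 stood apart in this list, at a mean of -0.25 against -0.060 to -0.026 in the other LDL samples, and without it the median was -0.055.

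Another 3 genes fell outside these lists. KIT, the stem cell factor receptor, fell from 65.92 ± 4.49 to 45.23 ± 4.19 CPM (SD, n = 4 each; 0.686 of control, edgeR adjusted p = 0.00526). IGFN1, an immunoglobulin and fibronectin domain gene, fell from 66.83 ± 2.37 to 48.01 ± 4.66 CPM (0.718 of control, edgeR adjusted p = 0.00818, n = 4 each). PTPRJ, a receptor tyrosine phosphatase, fell from 233.6 ± 3.87 to 192.8 ± 6.62 CPM (0.826 of control, edgeR adjusted p = 0.023, n = 4 each). KIT lies on chromosome 4 from 54657918 to 54740715, IGFN1 on chromosome 1 from 201190825 to 201228952 and PTPRJ on chromosome 11 from 47980558 to 48170841, each on the plus strand of GRCh38. The call of KIT was lost without control sample 3 (adjusted p = 0.0516), that of IGFN1 without control sample 1, 2 or 3 or LDL sample 2 (0.0522 to 0.0873) and that of PTPRJ without any control sample, LDL sample 2 or LDL sample 3 (0.0874 to 0.257). FPKM values with pseudocounts of 1 and 0.1 also lost IGFN1 (adjusted p = 0.197 and 0.204) and PTPRJ (adjusted p = 0.292 and 0.302), a pseudocount of 0.1 lost KIT (adjusted p = 0.055), and IGFN1 was the only gene of the 10 lost after GC and length correction (adjusted p = 0.212).

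PRSS53, a serine protease gene on the minus strand of chromosome 16 from 31083425 to 31089628, had the largest increase past the threshold. Its counts were 4, 11, 3 and 17 in control samples and 121, 102, 121 and 100 in LDL samples (0.212 ± 0.149 against 3.149 ± 0.285 CPM, SD, n = 4 each). The log2 fold change was 3.86 (SE 0.379, edgeR adjusted p = 0.000112). An annotated read-through gene, ENSG00000255439, overlaps it on the same strand from 31083439 to 31094956, and its counts were 143, 172, 201 and 307 in control samples and 0, 0, 13 and 0 in LDL samples. The read-through gene also overlaps VKORC1, on the same strand from 31090842 to 31095980. VKORC1 stood at 60.16 ± 2.37 CPM in control and 63.24 ± 4.78 CPM in LDL samples (SD, n = 4 each, edgeR adjusted p = 0.926). With the counts of PRSS53 and the read-through gene added, without VKORC1, the log2 fold change was -0.69 (SE 0.20, edgeR adjusted p = 0.546), so the sum did not rise.

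**Figure D3:**
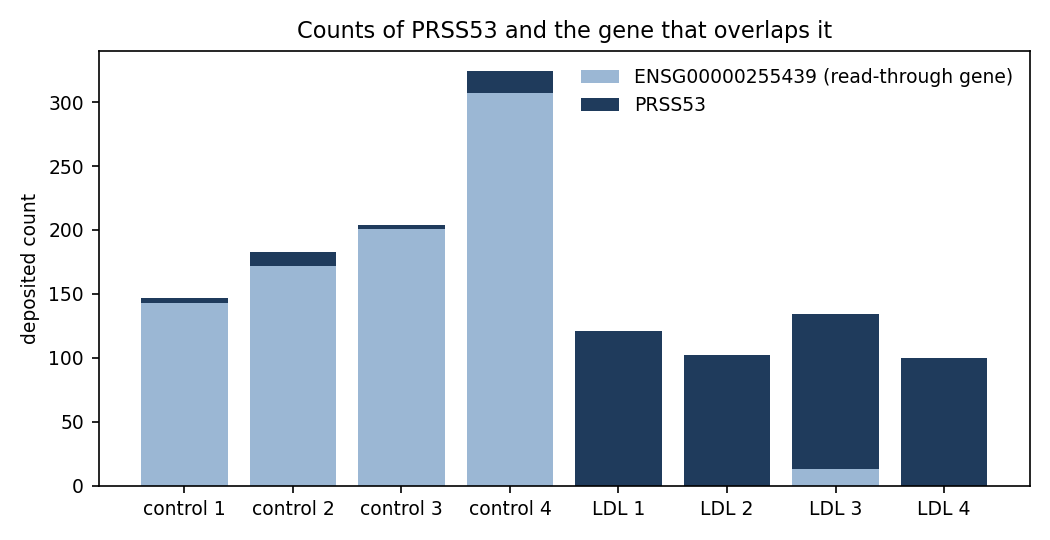
Deposited counts (y axis, stacked from 0) of PRSS53 and of the read-through gene ENSG00000255439 that overlaps it, for each of the 8 samples on the x axis. Added together they were 147, 183, 204 and 324 in control samples 1 to 4 and 121, 102, 134 and 100 in LDL samples 1 to 4.

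Because the title speaks of metastasis, lists for migration and invasion had been chosen in advance. None of 30 tested mesenchymal genes and regulators of the epithelial-mesenchymal transition (EMT) passed over all genes or over the list alone, and 15 lay above and 15 below 0. The median of this list was -0.013, its mean 0.046 and its test downward (camera adjusted p = 0.874). Its level per sample was -0.19 in LDL sample 4, 0.031 to 0.12 in the other LDL samples and -0.068 to 0.028 in the controls. Without LDL sample 4 the median was 0.0439 and the list was not called (camera adjusted p = 0.138 with a preset correlation). With each sample left out in turn the median ran from -0.102 to 0.0439. VIM, the intermediate filament vimentin, was at 1.09-fold, the transcription factor genes SNAI2 and ZEB1 at 1.01-fold and 1.02-fold, and POSTN, the matrix protein periostin, at 0.822 of control. Of 26 epithelial junction and keratin genes none passed (median -0.037, camera adjusted p = 0.707), with MUC1 at 1.17-fold. E-cadherin (CDH1) was low, with 115 counts over the 4 control and 34 over the 4 LDL libraries. LDL samples 2 and 3 had a count of 0. Its ratio, 0.344 of control, was the lowest in the list and did not pass (log2 fold change -1.54, edgeR adjusted p = 0.884). Of 28 matrix proteases and inhibitors none passed, and MMP24 was at 0.837 of control. The median of that list was -0.0061, its mean 0.021 and its test upward (adjusted p = 0.783). Wnt targets, with MYC at a log2 fold change of 0.17, had a median of -0.039 (adjusted p = 0.399). YAP targets had a median of -0.040 (adjusted p = 0.0723), with IGFBP3 and WWC1 lower when adjusted over the list alone; the list passed, lower, with DESeq2 (adjusted p = 0.0289), limma voom (adjusted p = 0.029), all FPKM fits (adjusted p from 0.0243 to 0.0382), sample weights (adjusted p = 0.0151) and without control sample 2 (adjusted p = 0.0265) or LDL sample 4 (adjusted p = 0.0182), all with a preset correlation; with an estimated one the adjusted p over all 8 samples was 0.37. NF-kB targets and cytokines had a median of 0.044 (adjusted p = 0.2), with CSF2 at a log2 fold change of 0.59, and without LDL sample 4 the list was called higher (0.115, adjusted p = 0.000131) with a preset correlation, while with an estimated one the adjusted p over all 8 samples was 0.706. Interferon-stimulated genes also had a median of 0.044 (adjusted p = 0.22), with BST2 at a log2 fold change of 0.13.

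**Figure D4:**
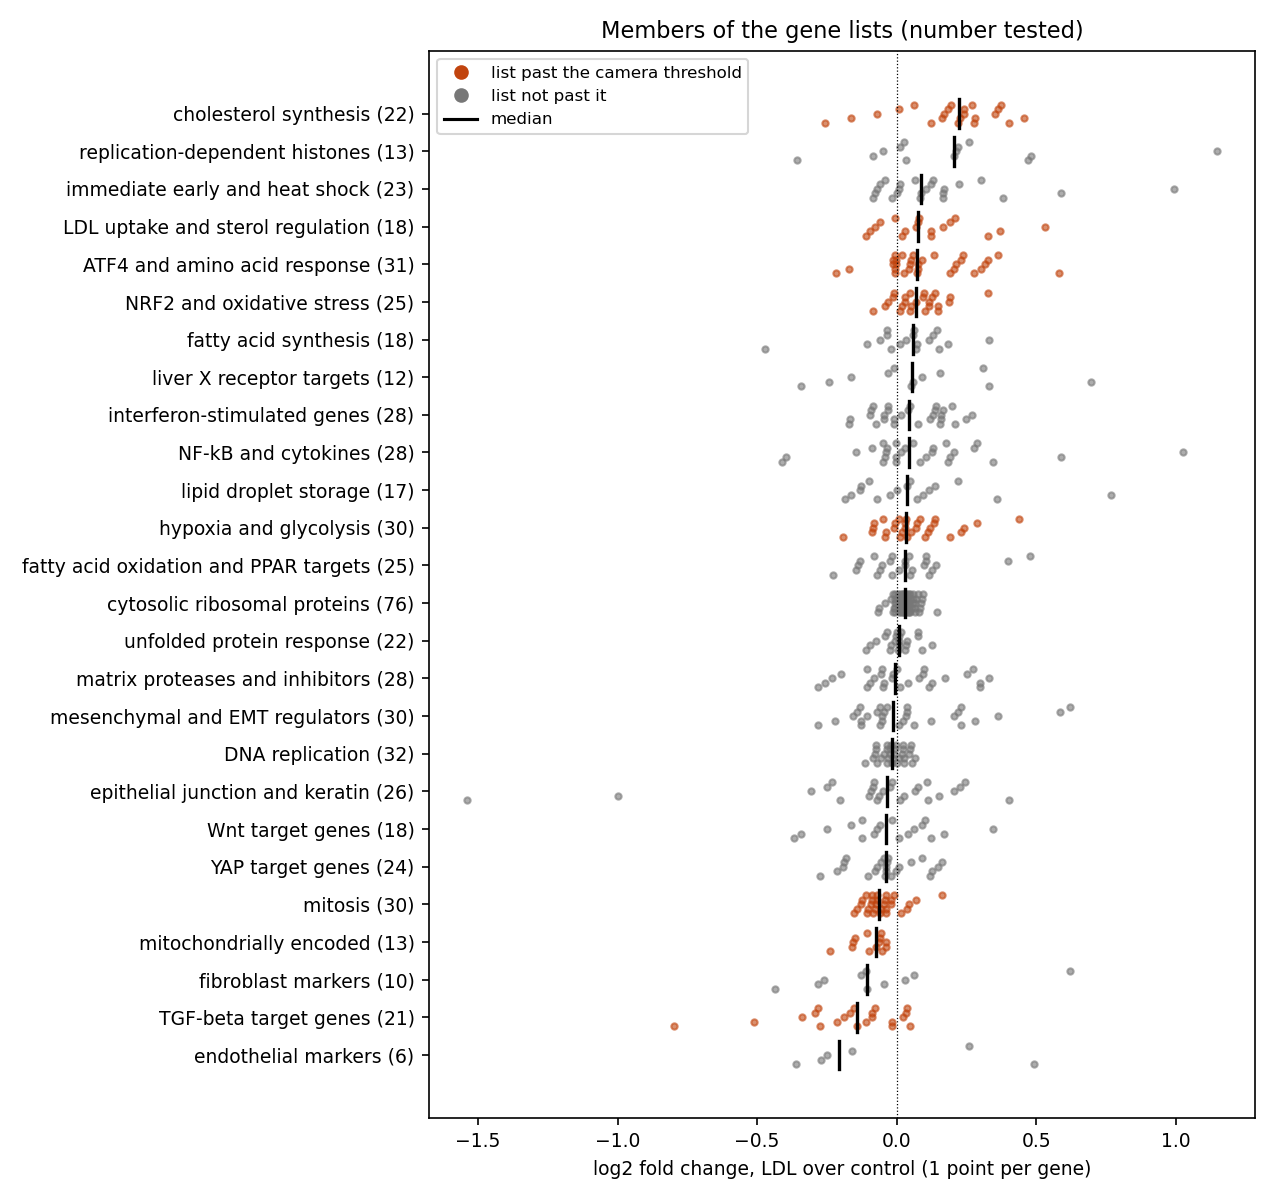
Log2 fold change of LDL over control (x axis) for each tested member of 26 of the 27 gene lists tested (y axis, number of tested members in brackets), with 1 point per gene and a bar at the list's median. Colour marks the 8 lists past the camera threshold with a preset correlation; the median was 0.22 for cholesterol synthesis, -0.14 for TGF-beta targets and -0.013 for mesenchymal and EMT regulators.

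Stress, metabolic and cell cycle lists showed shifts below 0.1 on the log2 scale. Mitosis genes were lower in 25 of 30 (median -0.065, camera adjusted p = 0.000556, and adjusted p = 0.37 with an estimated correlation), with the kinase gene AURKA at 0.899 of control. DNA replication genes had a median of -0.017 (adjusted p = 0.22). NRF2 targets of the antioxidant response had a median of 0.070 (adjusted p = 0.0142, and adjusted p = 0.37 with an estimated correlation), with ABCC3 at 1.14-fold. ATF4 and amino acid response genes had a median of 0.074 (adjusted p = 0.0142, and adjusted p = 0.446 with an estimated correlation), with DDIT4 at 1.28-fold. LDL sample 4 carried much of the ATF4 value, at a mean of 0.20 against -0.019 to 0.017 in the other LDL samples, and without it the median was 0.034 (adjusted p = 0.17). Without control sample 1 the ATF4 list was also lost (adjusted p = 0.0921), and the NRF2 list was lost without control sample 2 (adjusted p = 0.077), LDL sample 3 (adjusted p = 0.051) or LDL sample 4 (adjusted p = 0.0641) and after GC and length correction (0.0446, adjusted p = 0.0593). Sample weights also lost the ATF4 list (adjusted p = 0.0597). Hypoxia and glycolysis genes had a median of 0.035 (adjusted p = 0.0274, and adjusted p = 0.603 with an estimated correlation), with GAPDH at 1.09-fold and PFKFB3 at 0.876 of control. That call was lost without control sample 1 (adjusted p = 0.189), LDL sample 1 (adjusted p = 0.628) or LDL sample 2 (adjusted p = 0.107), without a count filter (adjusted p = 0.0893) and with FPKM values and pseudocounts of 1 and 0.1 (adjusted p = 0.0519 and 0.0508). Genes of the unfolded protein response had a median of 0.0063, a mean of 0.0044 and a downward test (adjusted p = 0.987), with HYOU1 at 0.926 of control. No single member of the lists in this paragraph passed over all genes or over its list alone.

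Check lists, most for other cell types, RNA quality or handling, gave the following, with 1 of them left out here and in the figure. Transcripts of the mitochondrial genome were lower in 13 of 13 (median -0.076, camera adjusted p = 5.21e-05, and adjusted p = 0.37 with an estimated correlation), and MT-ND4L (0.894 of control) and MT-ND5 were lower when adjusted over the list alone. The shift was uneven, with means of -0.12 and -0.13 in LDL samples 1 and 4 and 0.031 and 0.0073 in LDL samples 2 and 3. Ribosomal protein genes had a median of 0.028 (adjusted p = 0.147), with RPL13 at 1.06-fold, and their mean was -0.19 in LDL sample 1 against 0.019 to 0.12 in the other LDL samples. Without LDL sample 1 the list was called higher (median 0.0877, adjusted p = 1.02e-10), as it was with sample weights (0.0729, adjusted p = 3.02e-10), both with a preset correlation; with an estimated one the adjusted p over all 8 samples was 0.865. Replication-dependent histone genes had a median of 0.21 over 13 tested genes at low counts (adjusted p = 0.2), with H2BC8 at 0.199 and 0.435 CPM, and with 1 sample left out the median ran from 0.0192 to 0.209. Immediate early and heat shock genes had a median of 0.088 (adjusted p = 0.0648), and 2 members, KLF6 (log2 fold change 0.17) among them, were higher when adjusted over the list alone. The list was called higher without LDL sample 4 (0.162, adjusted p = 0.000128) or control sample 4 (0.127, adjusted p = 0.0229), with DESeq2 (adjusted p = 0.0284), limma voom (adjusted p = 0.0467) and sample weights (adjusted p = 0.011), and under some other filters, all with a preset correlation; with an estimated one the adjusted p over all 8 samples was 0.37. Fibroblast markers had a median of -0.11 (adjusted p = 0.147), and endothelial markers, with TIE1 at 0.571 and 0.803 CPM, had a median of -0.21 (adjusted p = 0.606). Leukocyte, erythroid and platelet, and hepatocyte markers had 4, 1 and 3 tested members, too few for the list test, and the members with the smallest p were CD68 (1.14-fold), ITGA2B (0.751 of control) and FGB (0.829 of control). The leukocyte antigen gene PTPRC had a count of 0 in all 8 libraries.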

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

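The tests of a mislabelled control and of the summed PRSS53 counts, the reading of sterol-regulated genes, the thinning, the GC and length correction and the position of left-out samples on 149 genes were chosen after the results they examine were seen.

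In 13 of 134 groups of 4 values, 1 sample lay far from the other 3, where chance gives about 5% of groups, or 7. LDL sample 4 stood apart in 3 list means, at -0.246 for TGF-beta targets (others -0.0597 to -0.0261), 0.196 for ATF4 and amino acid response genes (others -0.0185 to 0.0169) and -0.24 for immediate early and heat shock genes (others 0.116 to 0.179). It was also low in POSTN, at 18.92 CPM against 23.94 to 24.85 CPM. LDL sample 1 stood apart in RPL13 (935.3 CPM against 1017 to 1031 CPM) and in its total count of 36780334. LDL sample 2 was low in AURKA, at 108.7 CPM against 114.1 to 115.1 CPM. Control sample 2 was low in ID3 (129.6 CPM against 149.2 to 152 CPM) and in ANGPTL4 (31.21 CPM against 41.4 to 42.41 CPM). Control sample 3 was high in MYC (114.6 CPM), high in KLF6 (154.7 CPM) and low in the mean of matrix proteases and inhibitors (-0.0555). Control sample 4 had the highest share of mitochondrial counts, 2.99%.

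Cholesterol synthesis genes were higher in LDL samples, with a median log2 fold change of 0.22. In 1 of 35 splits of the 8 samples, the real one, the median was that far from 0, and the highest of the others was 0.135. That is the smallest share these splits can give. Since this list was 1 of 27 tested, the splits alone do not exclude chance. With 4 against 4 samples a permutation p adjusted over the 27 lists could hardly pass whatever the data, so it decides nothing here. Tests that can, adjusted over the same lists, gave an adjusted p of 0.0046 (camera with an estimated correlation) and 3.79e-05 (fry by direction). The lowest median with any 1 library left out was 0.191, after GC and length correction it was 0.211, and in libraries thinned to equal totals 0.22, which argues against a single library, composition bias or shallower LDL libraries as the whole cause. As a hypothesis, SREBP2 may be more active in the LDL samples: sterol-regulated genes outside the pathway had a median of 0.159 over 14 genes, of which 13 lay above 0 (camera adjusted p = 7.8e-07 over 3 such lists, and adjusted p = 0.0692 with an estimated correlation). Since added LDL is known to lower SREBP2 activity in many cells, the direction is a surprise. Whether the 2 groups differed in lipid supply at harvest was not tested. Growth state was read only through gene lists. Mitosis genes had a median of -0.065 (camera adjusted p = 0.000556 with a preset correlation and 0.37 with an estimated one). DNA replication genes had a median of -0.017 (camera adjusted p = 0.22), so a difference in growth state stays undecided.

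LDL sample 1 lay apart from the other LDL samples in the change between groups. Without it 149 genes were called in place of 10, and on the genes with the lowest p in the other 7 samples it lay at -14.2% of the way from control to LDL, where LDL samples 2, 3 and 4, each left out in the same way, lay at 75.3%, 69.0% and 56.0% and the controls at 8.04% to 33.8%. A mislabelled control is argued against by its mean of cholesterol synthesis genes, 0.128, the highest of the 8 libraries, where the controls lay between -0.131 and -0.0722, and by its ID3 level of 82.62 CPM, against 129.6 to 152 CPM in the controls. Correction for GC content and length moved its position to 9.45%, with the other LDL samples at 56.1% to 69.2% and the controls at 9.15% to 30.9%. Such bias may account for a part but not for the whole distance to the other LDL samples. The mean of cholesterol synthesis genes in LDL sample 1 also goes against a response that was weaker in all genes. The cause stays open.

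PRSS53 was higher in LDL samples by 3.86 on the log2 scale. The summed counts of PRSS53 and its read-through gene gave -0.695, so a different division of reads between overlapping genes is a candidate explanation of the call. The sum left out VKORC1, which the read-through gene overlaps too, so a division of reads with VKORC1 was not tested. A real change from the read-through transcript to PRSS53 would give the same counts and stays open, since estimated gene counts do not hold the junction reads that would separate them.

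The number of genes called, 10, was reached in 2 of 35 splits of the samples, so chance cannot be excluded for the count. The other split put control sample 1 with LDL samples 2, 3 and 4 and called 73 genes, several times the real count, which points to a structure of the samples beyond the groups. That split exchanges control sample 1 with LDL sample 1 and keeps the remaining samples of each group apart. Where each side held 2 control and 2 LDL samples, 0 to 3 genes were called. In the position test without correction LDL sample 1 lay at -14.2%, below every control. After correction for GC content and length it lay at 9.45%, just above the lowest control at 9.15% and far below the other LDL samples. Control sample 1, at 27.6% without and 20.1% with the correction, lay among the other controls. The structure therefore involves LDL sample 1, and why that sample stands apart is open. The number of lists called, 8, was reached in 2 of 35 splits, with 9 in the other, so chance cannot be excluded for that count either. Splits with 2 control and 2 LDL samples on each side called 0 to 5 lists with a preset correlation. Such list calls can therefore arise where the groups are evenly mixed.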

How the results depend on the processing

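FOXQ1 was higher in LDL samples under every setting run, with log2 fold changes from 0.48 to 0.74, and the median of cholesterol synthesis genes stayed above 0 and past the threshold under every setting run. FOXQ1 passed the threshold under 4 settings: DESeq2 (0.62), without LDL sample 1 (0.74), voom with sample weights (0.62) and an unadjusted p with a 1.5-fold change (0.62, by construction). With each sample left out in turn its log2 fold change ran from 0.481 to 0.738, the genes called from 2 to 149, those higher from 1 to 47, those lower from 1 to 102 and the lists from 5 to 10. Of the values of other named genes, 769 kept their direction and side of the threshold, 95 kept the direction and lost the threshold and 4 gained it; of the list medians 563, 33 and 23 did so.

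DESeq2 called 47 genes (17 higher, 30 lower). Limma voom called 8 genes (2 higher, 6 lower), of which 7 were among the 10 of the main test. FPKM values with a pseudocount of 0.1 gave 5 genes, 2 of them lower, and FPKM without a minimum 2 genes, 1 higher and 1 lower. A 2-fold threshold left 1 higher and 0 lower, and a test against a 1.2-fold change 2 genes, 1 each way, both by construction. Of the settings chosen after seeing the data, sample weights gave 27 genes (10 higher, 17 lower), GC and length correction 21 (7 higher, 14 lower) and an unadjusted p with a 1.5-fold change 113 (56 higher, 57 lower). With an estimated correlation 1 list was called, with fry 1 by direction and 5 in either direction. Except where the construction is named, the cause was not tested.

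The labels do not say whether same-numbered samples were paired. Deviations of same-numbered samples correlated at -0.101, 0.0602, 0.0321 and -0.00433 across genes, which gives no sign of pairing but cannot exclude it. With the replicate number as a block, 2 genes were called, 1 higher and 1 lower.

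PRSS53 reversed to -0.695 when its read-through gene was added, by construction. The other reversals were medians of lists that were not called, all within 0.11 of 0 except endothelial markers (-0.205). The unfolded protein response gave -0.00228 with upper-quartile factors, -0.00252 without a filter, -0.000139 with a mean of at least 1 CPM and -0.0157 after GC and length correction. Epithelial genes gave 0.0156 and 0.0159 with FPKM and pseudocounts of 1 and 0.1. After GC and length correction fatty acid oxidation gave -0.0123 and ribosomal proteins -0.0118. With 1 sample left out, the medians ran from -0.0155 to 0.0241 for the unfolded protein response, -0.102 to 0.0439 for EMT regulators, -0.079 to 0.0418 for epithelial genes, -0.0361 to 0.0393 for matrix proteases, -0.0132 to 0.113 for liver X receptor targets, -0.0104 to 0.115 for NF-kB and cytokines, -0.359 to 0.0151 for endothelial markers, -0.00738 to 0.0877 for ribosomal proteins and -0.174 to 0.00411 for fibroblast markers; the cause was not tested. At these depths the simulated test called 66.8% of genes changed by 1.5-fold, 78.4% at 2-fold and 93.2% at 4-fold. With 200 genes changed in the simulation, these shares may be too high for the data. Changes of each of these sizes can therefore be missed.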

Other observations

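The tests of sterol-regulated genes and of immediate early genes were chosen after the results were seen, and adjusted p values were put in place of unadjusted ones for these lists after the values were known, which changed 1 reading, that of the immediate early genes, from counting against a weaker response to undecided. All genes named below were chosen after their values were seen.

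Several genes lay close to the threshold. The kinase gene RIPK4 was at 0.796 of control (edgeR adjusted p = 0.0662). CITED4 (48.46 ± 2.81 against 62.14 ± 4.62 CPM, SD, n = 4 each; edgeR adjusted p = 0.066) and the glycosyltransferase gene B3GNT4 (7.083 ± 0.637 against 11.82 ± 2.39 CPM, SD, n = 4 each; edgeR adjusted p = 0.0662) were higher. DESeq2 called these 3 genes, along with SAMD11, DAPK1, FDFT1 and IDI1. Without LDL sample 1, edgeR also called the metallothionein genes MT1X and MT2A higher (1.31-fold and 1.47-fold), S100A6 higher (1.21-fold), and the basement membrane gene HSPG2 and the cholesterol exporter gene ABCA1 lower (0.787 and 0.716 of control). These calls were made without correction for GC content or transcript length.

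CYP26A1, which encodes the enzyme that clears retinoic acid, stood at 9.687 ± 0.619 CPM in control and 4.713 ± 1.57 CPM in LDL samples (SD, n = 4 each; 0.487 of control, edgeR adjusted p = 0.169). Lower retinoic acid signalling was tested on 15 other targets, whose median was -0.0155 (camera adjusted p = 0.78). Of these, 7 lay above and 8 below 0. The bound set in advance read a p of 0.05 or more as evidence against it, which was too strict, since a p that misses the threshold excludes nothing and a median near 0 over members that go both ways decides nothing, so the hypothesis cannot be told apart from no change.

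The 4 ID genes had a median log2 fold change of -0.47, and -0.494 after GC and length correction, which argues against composition bias. As a hypothesis, lower BMP signalling may account for it: 14 BMP targets other than ID genes had a median of -0.073 (camera adjusted p = 0.0276 over 3 such lists, and adjusted p = 0.0692 with an estimated correlation), with 9 below 0, among them SMAD6 and SMAD7, which the TGF-beta list holds too, and 5 above 0, with NOG the highest at 1.87-fold (edgeR adjusted p = 0.878). A weaker serum or handling response would lower immediate early genes as well, but their median was 0.0875 (camera adjusted p = 0.0648). Its list mean in LDL sample 4 was -0.24 against 0.116 to 0.179 in the other LDL samples and -0.161 to 0.0282 in the controls. Without that sample the median was 0.162 (adjusted p = 0.000128), and DESeq2 and limma voom also called the list higher (adjusted p = 0.0284 and 0.0467), all with a preset correlation; with an estimated one the adjusted p over all 8 samples was 0.37. The direction goes against a weaker response, while the main test missed the threshold and LDL sample 4 lay below every control, so the explanation is left open.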
